A study of Homo sapiens with 12 samples.

How the data were processed

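RNA sequencing of DU145 cells was analysed from 12 libraries in 4 groups of 3: vehicle (Ctrl), triptolide (TPL), decitabine (DAC) and both drugs (DACTPL). Total RNA libraries were stranded and sequenced in paired reads of 100 bases, per the labels' protocols. The deposited expression table gave expected counts and TPM per gene for each library, made by the authors with RSEM 1.2.09 on hg19, per the submitters' processing notes. The aligner, the gene annotation, the strand setting and the treatment of multiply mapped reads were not given in the sources used here. The authors' deposited tables of comparisons gave log2 fold changes and p-values from DESeq2 under R 4.0.4, per the submitters' processing notes and the file headers. A further deposited table gave a z-score per gene and sample for a list of genes chosen by the authors, and this score was used here to identify the listed genes and the group with the highest mean score.

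Expected counts divide a read that fits several genes between them, and 64.3% of the deposited values lay within 0.005 of a whole number. They were rounded to whole numbers before testing. Members of near-identical families (GAGE, MAGEA, SSX, XAGE), readthrough transcripts and overlapping or antisense genes are uncertain where reads could be divided between them, and 37 tested entries repeated the counts of another entry. Of 26341 genes, 5761 had no counts in any library. A further 28 symbols had been turned into dates in the deposited table, 27 of which were resolved from the reference gene names. The reference at hand was an assembly other than hg19 and was used for gene names and gene classes alone, so no coordinates are given. The small structural RNAs (snoRNAs, scaRNAs, microRNA precursors and RPPH1 among them) were recognised by symbol.

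Differences were tested with edgeR 4.0.16 under R 4.3.3, using TMM normalization, filterByExpr by group, a robust quasi-likelihood fit over all 12 libraries and Benjamini-Hochberg adjustment over the 15890 genes that passed the filter. A gene was called at an adjusted p below 0.05, two-sided. The 7 comparisons were DAC, TPL and DACTPL each against Ctrl, DACTPL against DAC and against TPL, the interaction (DACTPL minus TPL minus DAC plus Ctrl) and the mean of the 3 treated groups against Ctrl. The biological coefficient of variation was 9%. Where a group had no counts, the fold is a lower bound against 3 counts per library, and with 1 to 3 counts over a group the ratio is given with its 95% counting interval. Depth, in M expected counts per library, ranged from 26.4 to 47, and TMM factors from 0.957 to 1.028.

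A total of 25 gene lists was fixed by symbol before the data were examined, as were the groups, the tests, most of the alternatives and the rule for the genes named. Each list with at least 5 tested members was tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation, fry and counts adjusted over the list alone were added. The genes named are DCTPP1, DNMT1, DNMT3A, DNMT3B, DCK and ERCC3 in every case. Added were, for DAC vs Ctrl, DACTPL vs Ctrl and DACTPL vs DAC the 8 rises and 8 falls with the largest absolute log2 fold change, and 5 of each for TPL vs Ctrl, DACTPL vs TPL and the interaction. These were taken among called genes with at least 1 CPM in the higher group and all 3 libraries of one group above all 3 of the other. From each list with calls came up to 4 members with the largest absolute log2 fold change and at least 1 CPM. A list reported without calls gave up to 2 members with the highest mean CPM, values only. Unnamed gene models and further members of a family after the first 2 were passed over, and the comparison of all treated libraries with Ctrl names no genes of its own. The text prints a selection of these genes, and some genes chosen by the rule are not reported here.

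The slope of one decitabine response on the other was a total least squares slope through the origin, with a jackknife error over libraries. Overlaps of calls were set beside the expectation for independent lists, and correlations of fold changes beside groups simulated without change. All 12 libraries of that simulation, Ctrl included, were drawn gene by gene from the Ctrl means and the fitted dispersions. The cancer-testis score was the mean log2 CPM of tested members per library, compared by an exact permutation test. Relative gene lengths were derived from the deposited counts and TPM. For the histone list the trend of the fold changes on length over coding genes was also taken off within a comparison. The edgeR procedure was tested on simulated data with known changes, drawn from the means, library sizes and dispersions of the real samples. For DAC vs Ctrl it recovered 16%, 58%, 80% and 96% of changes of 1.25-, 1.5-, 2- and 4-fold (50 genes of each size). Of 138 calls in that simulation, 13 were of unchanged genes. With DESeq2 these were 34 of 166 calls.

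Alternatives were DESeq2 1.42.0, RLE size factors, no expression filter, and a filter of 1 CPM in 3 libraries. Others were limma on log2(TPM + 1) and log2(TPM + 0.1), fits of the compared groups alone, other thresholds and each library left out in turn. Added after seeing the data were TPM rescaled by each library's median ratio, repeated entries counted once, small structural RNAs left out, and the replicates numbered 3 left out together. So were each library's trend of expression with gene length over coding genes taken off, and list medians under each scaling. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.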

Results

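Total RNA was sequenced from DU145, an androgen receptor negative prostate cancer line established from a brain metastasis. Cells were given vehicle (Ctrl), triptolide at 2 nM (TPL), decitabine at 33 nM (DAC) or both drugs (DACTPL) on 3 consecutive days and were then grown without drug for 17 days. Decitabine is a cytidine analogue that is built into DNA and traps DNA methyltransferases. Triptolide binds the ERCC3 helicase of the transcription factor TFIIH. The study asked whether triptolide makes cancer cells more sensitive to nucleoside inhibitors of DNA methylation through DCTPP1, a pyrophosphatase that hydrolyses dCTP analogues. For the combination, the sample characteristics gave 33 nM decitabine and the treatment protocol gave 3 nM, so the decitabine dose in DACTPL was not settled.

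Each of the 4 groups had 3 libraries. Total expected counts, in M, were 38.6, 29.1 and 47 in Ctrl, 26.4, 31 and 31.8 in TPL, 37.5, 32.8 and 43.7 in DAC, and 42.5, 32.4 and 31.5 in DACTPL. Of 26341 genes, 15890 passed the expression filter and were tested. The labels did not state that replicates were separate cultures, so p-values measured only the spread between these samples, which may be technical. Counting intervals and floors covered counting error only. Values in CPM are given as mean ± SD with n = 3 libraries per group, and log2 fold changes with their standard error (SE). Rises and falls passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05.

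The libraries differed in short transcripts. Small structural RNAs, mainly small nucleolar RNAs and the RNase P RNA RPPH1, took 2.21 ± 0.137% of the counts in Ctrl, 4.13 ± 0.638% in TPL, 2.84 ± 0.0954% in DAC and 3.12 ± 0.251% in DACTPL (SD, n = 3). Across 14128 protein-coding genes, a library's deviation from the mean of all libraries was related to gene length with a Spearman correlation of 0.24, 0.16 and 0.24 in Ctrl, -0.38, -0.37 and 0.16 in TPL, -0.21, -0.31 and 0.09 in DAC, and -0.20, 0.28 and 0.22 in DACTPL, in the order of replicates 1 to 3. These correlations are across genes, which are not independent replicates.

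**Figure D1:**
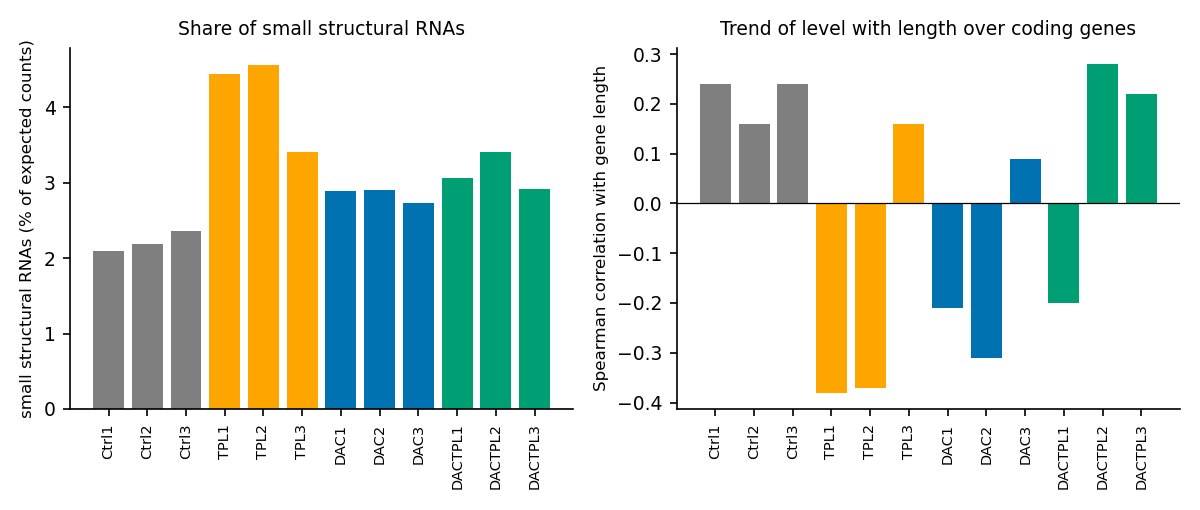
Share of counts in small structural RNAs (percent) and Spearman correlation of expression with gene length for each of the 12 libraries. TPL replicates 1 and 2 had the highest small RNA shares (4.44% and 4.56%) and the most negative length correlations (-0.38 and -0.37).

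The comparison of DAC with Ctrl asked which genes still differed 17 days after decitabine was withdrawn. Germline genes without counts in vehicle-treated cells were expressed after decitabine. MAGEB2, a cancer-testis antigen of the MAGE family, had 0 counts in all 3 Ctrl libraries and 5.94 ± 0.856 CPM in DAC, at least 74.6-fold higher against a floor of 3 counts per library (edgeR adjusted p = 1.3e-06). GTSF1, a factor of the piRNA pathway that silences transposons in the germ line, reached 8.11 ± 1.08 CPM and was at least 102-fold higher (adjusted p = 3.73e-07). GAGE2D was at least 114-fold higher, MAGEA6 at least 14.3-fold and GAGE1 at least 14.0-fold, although counts within the near-identical GAGE and MAGEA families could be split between copies and are uncertain for a single member. MAEL, another piRNA factor, had 3 counts over the Ctrl libraries and a ratio of 70.9 (95% counting interval 23.9 to 347). LIN28B, an RNA-binding protein of germ and embryonic cells, rose by a log2 fold change of 3.75 (SE 0.35, adjusted p = 2.14e-05).

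Of 30 cancer-testis antigens tested, 19 rose and 11 did not pass (21 rose when adjusted over the list alone). Their summed level was 112 ± 0.638 CPM in Ctrl and 135 ± 9.67 CPM in DAC. As a group they ranked above other genes (camera adjusted p = 6.7e-20, and adjusted p = 0.046 with an estimated correlation). The filter shaped this rank, since 30 of the 83 list members in the table were tested. A member silent in Ctrl and TPL passed only where a decitabine group expressed it, so it could only come out higher. Members with at least 10 counts numbered 8 in each Ctrl library and 27 to 34 in the DAC libraries. The list median, 6.66 in the main fit, ranged from 0.17 to 6.83 over the alternatives. It was 0.57 on log2(TPM + 1) and 2.14 on log2(TPM + 0.1), so its size depended on the amount added to silent genes. Of 28 germline, meiosis and piRNA genes, 11 rose and 1 fell (14 and 4 adjusted over the list alone; camera adjusted p = 2.1e-04, and adjusted p = 0.16 with an estimated correlation). With the stricter filter the germline list was not called in DAC vs Ctrl (adjusted p = 0.29), its median going from 0.53 to 0.00. GFRA1, a receptor for a glial neurotrophic factor, was also without counts in Ctrl and was at least 15.6-fold higher at 1.24 ± 0.323 CPM, and GPAT2, an acyltransferase of the testis, had 1 count in Ctrl and a ratio of 116 (counting interval 20.4 to 4620). EEF1E1-BLOC1S5, a readthrough of neighbouring genes whose counts overlap theirs and are uncertain, had 0 counts in Ctrl, TPL and DACTPL and 2.64 ± 1.96 CPM in DAC.

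Interferon-stimulated genes rose together after decitabine. IFI27, an interferon-induced mitochondrial protein, went from 0.537 ± 0.0606 CPM in Ctrl to 9.88 ± 0.575 CPM in DAC (18.3-fold, edgeR adjusted p = 3.97e-09). OASL, a relative of the oligoadenylate synthetases, went from 13.2 ± 1.86 to 84.7 ± 2.41 CPM (6.38-fold, adjusted p = 8.02e-09), and BST2, which tethers budding viruses, rose 8.15-fold from 0.154 ± 0.0421 CPM. Of 52 genes of this list, 33 rose and 19 did not pass (43 rose when adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 2.4e-28, and adjusted p = 0.082 with an estimated correlation). MHC class I antigen presentation moved less, with 6 of 20 members higher (9 adjusted over the list alone) and a median of 0.22 (camera adjusted p = 6.8e-05, and adjusted p = 0.14 with an estimated correlation). The peptide transporter TAP1 went from 55.5 ± 1.21 to 72.9 ± 2.95 CPM.

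**Figure D2:**
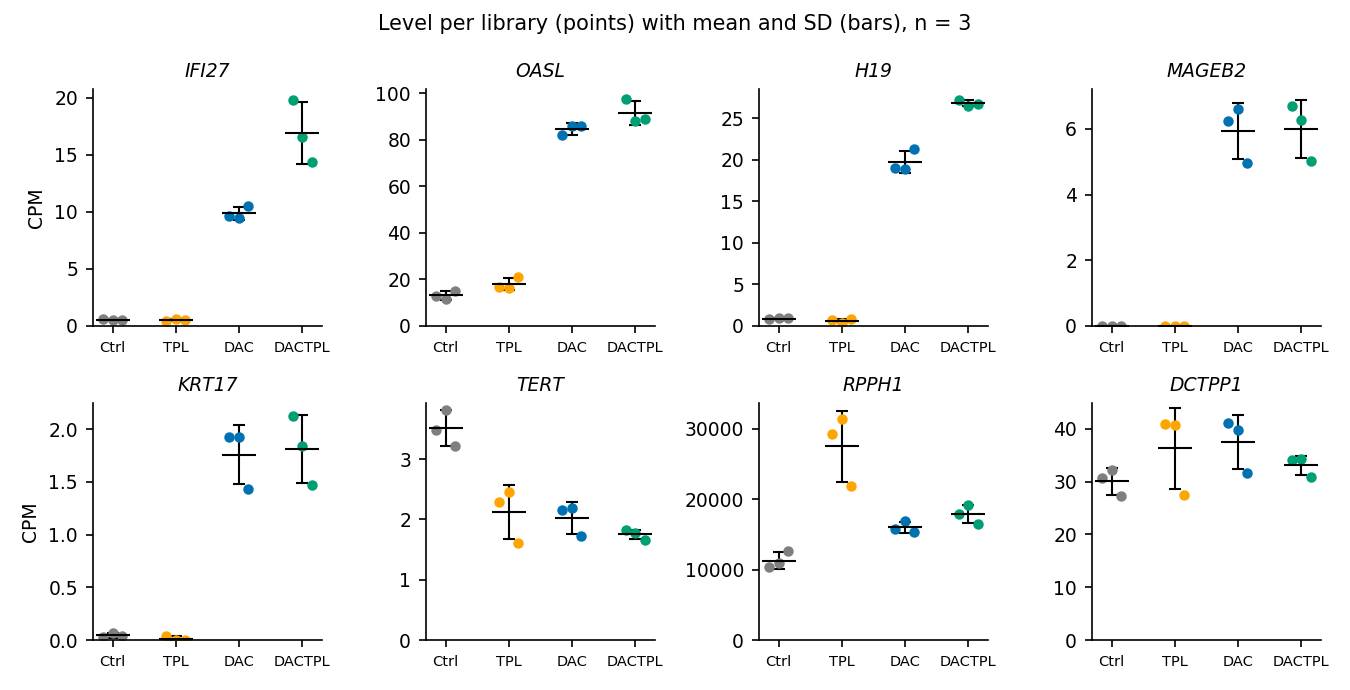
CPM in each library for IFI27, OASL, H19, MAGEB2, KRT17, TERT, RPPH1 and DCTPP1, with each point a library, and the mean and SD of the 3 libraries per group. IFI27 averaged 9.88 CPM in DAC and 16.9 CPM in DACTPL against 0.537 CPM in Ctrl and 0.527 CPM in TPL, whereas DCTPP1 lay between 30.1 and 37.6 CPM in the group means.

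Several single genes outside these groups rose as well. H19, an imprinted noncoding RNA, rose 22.0-fold from 0.891 ± 0.077 to 19.7 ± 1.33 CPM (log2 fold change 4.46, SE 0.13, edgeR adjusted p = 7.33e-10), and DIRAS3, an imprinted GTPase, rose by 1.12 on the log2 scale. KRT17, a basal keratin with 5 counts over the Ctrl libraries, rose by 5.25 (SE 0.37), and the keratin KRT81 went from 34.6 ± 3.35 to 87.7 ± 14.2 CPM. Among glycolytic genes, the aldolase ALDOC rose by 2.92 (SE 0.16, adjusted p = 1.23e-07) and the glucose transporter SLC2A3 by 2.00 (SE 0.14). S100A4, a calcium-binding protein of migrating cells, rose by 1.84 (SE 0.12), and TFPI2, a protease inhibitor gene often methylated in tumours, went from 22.6 ± 2.18 to 75.4 ± 10.6 CPM.

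By list, 4 of 23 imprinted genes rose and 1 fell, and 7 of 37 genes hypermethylated in prostate cancer rose (adjusted over the list alone, 6 and 2, then 7 and 1). Of 25 mesenchymal genes 6 rose (8 adjusted over the list alone), with a median log2 fold change of 0.20 (camera adjusted p = 0.0092, and adjusted p = 0.10 with an estimated correlation). Of 30 hypoxia and glycolysis genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), and of 29 epithelial genes 5 rose and 4 fell (7 and 6), whose median of -0.01 and mean of 0.41 differed in sign. Heat shock genes had a median of 0.13, with 3 of 23 higher (8 adjusted over the list alone; camera adjusted p = 0.0023, and adjusted p = 0.065 with an estimated correlation).

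Cholesterol synthesis ran the other way. Of 26 genes of the pathway 6 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 6.6e-06, and adjusted p = 0.42 with an estimated correlation). Their summed level was 6050, 6102 and 7351 CPM in Ctrl and 5315, 5339 and 6790 CPM in DAC. In both groups replicate 3 was the highest, and DAC replicate 3 lay above Ctrl replicates 1 and 2. HMGCS1, which makes the precursor of mevalonate, fell from 234 ± 11.8 to 187 ± 19.1 CPM, and the sterol demethylase CYP51A1 from 330.2 ± 13.9 to 266 ± 16.3 CPM. The largest falls elsewhere were smaller than the largest rises. PADI1, a peptidylarginine deiminase, fell by 1.26 on the log2 scale from 3.73 ± 0.517 CPM (SE 0.18, edgeR adjusted p = 7.14e-04). CALB2, which encodes calretinin, fell by 1.11 from 7.82 ± 1.18 CPM. The macrophage marker CD68, not among the largest falls, fell by 0.47 from 38.8 ± 1.93 CPM.

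Replication-dependent histone genes were higher in DAC, with 24 of 52 called (40 adjusted over the list alone) and a median log2 fold change of 0.37 (camera adjusted p = 1.6e-19, and adjusted p = 0.20 with an estimated correlation). HIST1H4L went from 3.62 ± 0.207 to 7.92 ± 1.73 CPM and HIST1H2BM from 4.26 ± 0.278 to 7.74 ± 0.0971 CPM. Fold changes in this comparison were related to gene length (Spearman -0.30 across coding genes), and with each library's length trend taken off, 15 histone genes were called with a median of 0.15.

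Among the genes the study was about, DNMT3B, a de novo DNA methyltransferase, rose from 6.29 ± 0.439 to 8.57 ± 0.186 CPM (log2 fold change 0.45, SE 0.08, edgeR adjusted p = 0.00301). DCTPP1 was at 30.1 ± 2.55 CPM in Ctrl and 37.6 ± 5.09 CPM in DAC and did not pass (0.32, SE 0.14, adjusted p = 0.178). DNMT1 (0.00, SE 0.06), DNMT3A (-0.05, SE 0.10), the kinase that activates decitabine, DCK (0.03, SE 0.13), and ERCC3 (0.00, SE 0.05) did not pass either. The other lists held few calls. Of 17 genes of the DNA methylation machinery 2 rose, of 27 p53 targets 4 rose, of 40 proliferation genes 3 rose, of 34 DNA repair genes 1 rose and of 24 TFIIH and RNA polymerase II genes 3 rose. Of 26 ATF4 and unfolded protein response genes 3 rose and 1 fell, and of 27 NF-kB and cytokine genes 2 rose and 1 fell. Adjusted over the list alone, the higher and lower counts of these 7 lists were 2 and 1, 6 and 0, 0 and 0, 0 and 0, 5 and 0, 3 and 2, and 5 and 1. None of the 17 nucleoside drug handling genes was called by edgeR, also when adjusted over the list alone (3 at an unadjusted p under 0.05, 1 by DESeq2).

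Markers of other cell types were looked at as well. Of 6 stromal markers 3 rose, their summed level going from 21.7 ± 1.53 CPM in Ctrl to 25.9 ± 4 CPM in DAC. The groups overlapped, with DAC replicate 1 at 22.55 CPM and Ctrl replicate 3 at 23.47 CPM. Of 6 blood markers 1 rose and 1 fell, 1 of 8 luminal prostate markers fell, and none of 3 intestinal markers passed with edgeR, DESeq2 or an unadjusted p under 0.05. The summed blood level went from 47.2 ± 2.37 CPM in Ctrl to 36.8 ± 2.52 CPM in DAC. Adjusted over the list alone, 4 stromal markers rose and 1 fell, 2 blood markers rose and 1 fell, 2 luminal markers fell, and the intestinal count stayed at 0. Mitochondrially encoded transcripts had 0 members among the tested genes.

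In all, 1566 genes differed between DAC and Ctrl, 996 higher and 570 lower, and 370 of them by 2-fold or more (343 higher and 27 lower). With limma on log2(TPM + 1) the split of 1651 genes was 623 higher and 1028 lower. Without Ctrl replicate 1, 753 genes were called, without Ctrl replicate 2, 806, without DAC replicate 1, 963, and without DAC replicate 2, 779.

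**Figure D3:**
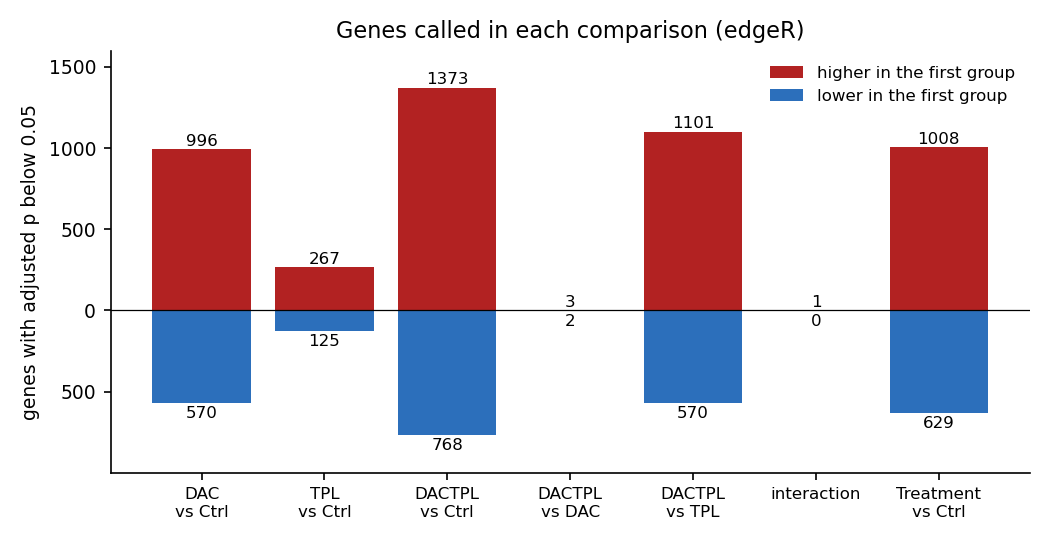
Number of genes higher and lower at an adjusted p below 0.05 in each of the 7 comparisons, as bars from 0. DACTPL vs Ctrl had the most calls (1373 higher and 768 lower) and the interaction the fewest (1 higher).

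Triptolide alone was compared with vehicle to ask what the drug left behind after 17 days. The largest rises were short structural RNAs. RPPH1, the RNA subunit of RNase P, went from 11290 ± 1200 CPM in Ctrl to 27470 ± 5010 CPM in TPL (log2 fold change 1.28, SE 0.13, edgeR adjusted p = 4.91e-04). SCARNA5, a guide RNA of Cajal bodies, went from 15.8 ± 0.947 to 43.7 ± 6.68 CPM (1.47, SE 0.12, adjusted p = 3.97e-04). SCARNA10 rose by 1.25 and SNORA43, a guide of RNA pseudouridylation, by 1.88 (SE 0.37, adjusted p = 0.0327). TERT, the catalytic subunit of telomerase, fell from 3.51 ± 0.299 to 2.12 ± 0.448 CPM (adjusted p = 0.0363). Of 96 small structural RNAs tested, 29 rose and 1 fell, 85 lay above 0, and the median was 0.60.

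Coding genes moved by smaller amounts. Of 34 DNA repair genes 4 fell (6 adjusted over the list alone; median -0.11, camera adjusted p = 6.2e-05, and adjusted p = 0.49 with an estimated correlation), among them XRCC2, which acts in homologous recombination (22.3 ± 2.13 to 16.4 ± 0.889 CPM, edgeR adjusted p = 0.0194), and BRCA2 (87.6 ± 11.4 to 67.7 ± 4.39 CPM). Of 40 proliferation genes, the centromere proteins CENPF and CENPE fell, also when adjusted over the list alone (2 genes; median -0.10, camera adjusted p = 3.4e-04, and adjusted p = 0.57 with an estimated correlation). LIF, a cytokine, fell by 0.38 (SE 0.07) in the NF-kB and cytokine list, of which it was the 1 member called, also adjusted over the list alone (median -0.16, camera adjusted p = 0.010, and adjusted p = 0.50 with an estimated correlation). Without TPL replicate 3 the proliferation list (median -0.04, adjusted p = 0.76) and the NF-kB list (median -0.11, adjusted p = 0.36) were not called, nor were they without the replicates numbered 3 of all groups.

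Groups that lay above 0 were the histones, class I antigen presentation, interferon-stimulated and cholesterol genes. Histone genes rose in 5 of 52 cases (18 adjusted over the list alone; median 0.23, camera adjusted p = 6.3e-10, and adjusted p = 0.50 with an estimated correlation), with HIST1H1B going from 181 ± 4.71 to 260.1 ± 44.4 CPM. The summed histone level was 4768 and 4882 CPM in TPL replicates 1 and 2 and 3886 CPM in TPL replicate 3, near the 3719 to 3830 CPM of the Ctrl libraries, and without TPL replicate 3 the median was 0.38. The immunoproteasome subunit PSMB8 was among the class I genes that rose (2 of 20, and 8 adjusted over the list alone; median 0.24, camera adjusted p = 2.9e-06, and adjusted p = 0.28 with an estimated correlation). OASL, IFI35 and ISG20 rose among 52 interferon-stimulated genes (3, and 6 adjusted over the list alone; median 0.18, camera adjusted p = 3.4e-04, and adjusted p = 0.53 with an estimated correlation). Without TPL replicate 3 the interferon list was not called (median 0.05, adjusted p = 0.11). In cholesterol synthesis 0 of 26 genes were called by edgeR over all genes, 6 adjusted over the list alone, 9 at an unadjusted p under 0.05 and 4 by DESeq2 (median 0.13, camera adjusted p = 3.1e-05, and adjusted p = 0.50 with an estimated correlation). The summed cholesterol level of TPL replicates 1 and 2, 6695 and 6577 CPM, lay below Ctrl replicate 3 at 7351 CPM, and TPL replicate 3 was at 7913 CPM. On the TPM scale as deposited, where the median of all genes tested moved to -0.29, these 4 medians turned to -0.15, -0.12, -0.10 and -0.23, above that of all genes.

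Smaller shifts were called for the TFIIH and RNA polymerase II list (2 of 24 higher, POLR2F and POLR2L, and 4 adjusted over the list alone; camera adjusted p = 0.0096, and adjusted p = 0.50 with an estimated correlation). So were they for epithelial genes (1 of 29, the vesicle protein MAL2, and 3 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.28 with an estimated correlation), and hypoxia and glycolysis genes (1 of 30, the glycolytic kinase PGK1, also adjusted over the list alone; camera adjusted p = 0.0096, and adjusted p = 0.53 with an estimated correlation). Medians of these lists were 0.06, 0.09 and 0.10. They turned to -0.29, -0.25 and -0.20 on the TPM scale as deposited, where all genes tested had a median of -0.29. On rescaled TPM they were 0.05, 0.04 and 0.04. The TFIIH call was lost without Ctrl replicate 3 or TPL replicate 2, the epithelial call without Ctrl replicate 3, TPL replicate 1 or TPL replicate 2, and the hypoxia call without TPL replicate 3 (adjusted p = 0.14). The DNA methylation machinery had a median of -0.08 and 0 of 17 genes called by edgeR, 2 lower adjusted over the list alone, 4 at an unadjusted p under 0.05 and 2 by DESeq2 (camera adjusted p = 0.020, and adjusted p = 0.32 with an estimated correlation), a list call lost without TPL replicate 1 or TPL replicate 2. No cancer-testis antigen was called by edgeR or DESeq2, with 1 at an unadjusted p under 0.05. DCTPP1 stood at 36.3 ± 7.69 CPM in TPL (log2 fold change 0.27, SE 0.14, adjusted p = 0.332), DNMT1 at 215 ± 10 CPM (-0.13, SE 0.06, adjusted p = 0.228) and ERCC3 at 41.2 ± 1.35 CPM (0.04, SE 0.05, adjusted p = 0.709). None of them passed.

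Some of these changes went with gene length. Fold changes of TPL against Ctrl were related to length with a Spearman correlation of -0.36 across coding genes, so that short genes lay higher. With each library's length trend taken off, a correction chosen after the data were seen, 135 of the 392 calls remained. RPPH1 (1.02, SE 0.09), SCARNA5 (1.21, SE 0.12), SCARNA10 (0.99, SE 0.07), XRCC2 (-0.45), LIF (-0.36), POLR2F (0.34), MAL2 (0.34) and HIST1H1B (0.34) were among those kept. The trend was fitted on coding genes, and 18 of 96 small structural RNAs lay inside their length range. Shorter genes took the value at the short end of the trend. For such RNAs a kept call therefore does not exclude a difference in size selection. Calls also ended where the fold stayed near its value, as for TERT (-0.72, SE 0.16, to -0.70, SE 0.17), OASL (0.45, SE 0.11, to 0.41, SE 0.11), PGK1 (0.45, SE 0.10, to 0.43, SE 0.10) and SNORA43 (1.88, SE 0.37, to 1.61, SE 0.35). Folds shrank further for CENPF (-0.32, SE 0.07, to -0.18, SE 0.09), BRCA2 (-0.37, SE 0.08, to -0.21, SE 0.12) and POLR2L (0.35, SE 0.07, to 0.20, SE 0.08), and IFI35, ISG20, PSMB8 and CENPE were no longer called either.

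The histone median went to 0.00 with 1 gene called (camera adjusted p = 0.84). The camera calls of TFIIH and RNA polymerase II genes (median 0.04, adjusted p = 0.19) and of the DNA methylation machinery (median -0.02, adjusted p = 0.39) ended too. Other lists kept a camera adjusted p below 0.05 after the correction, with medians of 0.16 for interferon-stimulated genes (adjusted p = 3.5e-04), 0.16 for class I genes (7.9e-06), -0.09 for proliferation (1.4e-04), -0.08 for DNA repair (0.0069), 0.13 for cholesterol synthesis (1.2e-05), -0.18 for NF-kB and cytokine genes (5.9e-04), 0.08 for epithelial genes (0.026) and 0.06 for hypoxia and glycolysis (0.0069). These used the preset correlation. Before the correction none of them was called by camera with an estimated correlation (adjusted p from 0.28 to 0.57). EdgeR then called 0 interferon, class I and proliferation genes (before the correction, at an unadjusted p under 0.05, 15 higher and 1 lower, 11 higher and 9 lower, and 7, 5 and 2 by DESeq2) and 1 DNA repair, 1 cholesterol and 1 NF-kB gene.

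The 392 genes called between TPL and Ctrl comprised 267 higher and 125 lower, 30 of them by 2-fold or more. DESeq2 called 848, and limma on log2(TPM + 1) called 10270, of which 62 were higher and 10208 lower. The count was 25 without Ctrl replicate 2, 29 without Ctrl replicate 1, 47 without TPL replicate 2, 56 without TPL replicate 1, 199 without DAC replicate 2, 201 without DACTPL replicate 3, 245 without DAC replicate 1, 618 without Ctrl replicate 3 and 930 without TPL replicate 3. SCARNA5 and RPPH1 were the named genes called under each of the 24 alternatives that kept them in the test, which leaves aside the omission of small structural RNAs.

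The combination was compared with vehicle to ask what both drugs left together, with the decitabine dose unsettled between 33 nM and 3 nM. Germline and interferon genes again rose. MAGEB2 was at 6 ± 0.872 CPM, at least 75.4-fold higher than in Ctrl (edgeR adjusted p = 1.07e-06), GTSF1 was at least 91.8-fold higher and MAGEA1, with counts uncertain between family members, at least 14.8-fold. Of 30 cancer-testis antigens 19 rose and 11 did not pass (23 rose and 1 fell adjusted over the list alone; camera adjusted p = 1e-18, and adjusted p = 0.053 with an estimated correlation). Germline genes rose in 13 of 28 cases and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 5.4e-05, and adjusted p = 0.13 with an estimated correlation), a list call lost with the stricter filter (adjusted p = 0.16).

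IFI27 reached 16.9 ± 2.72 CPM in DACTPL, a log2 fold change of 4.97 over Ctrl (SE 0.16, edgeR adjusted p = 5.25e-10). Of 52 interferon-stimulated genes 43 rose and 9 did not pass (44 and 1 lower adjusted over the list alone), with a median of 1.06 (camera adjusted p = 4.6e-35, and adjusted p = 0.072 with an estimated correlation). Class I antigen presentation rose in 11 of 20 genes (14 adjusted over the list alone; median 0.30, camera adjusted p = 6e-07, and adjusted p = 0.093 with an estimated correlation), with HLA-B going from 241 ± 22.8 to 371 ± 6.84 CPM and B2M, the light chain of class I, from 539 ± 50.1 to 809.9 ± 66.9 CPM. CCL5, a chemokine, rose by 0.75 (SE 0.13, adjusted p = 0.00265) in a list of 27 NF-kB and cytokine genes of which 4 rose and 3 fell (the same numbers adjusted over the list alone).

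H19 reached 26.8 ± 0.355 CPM (log2 fold change 4.90, SE 0.13, edgeR adjusted p = 1.98e-10), DIRAS3 rose by 2.04 and KRT17 by 5.30, ALDOC by 3.26 and SLC2A3 by 2.41. AXL, a receptor tyrosine kinase of mesenchymal tumour cells, fell from 1117 ± 119 to 699.9 ± 50.3 CPM (adjusted p = 0.00817). The list of 25 mesenchymal genes was mixed and was not called by camera. Its median was 0.21, with 8 genes higher and 1 lower by DESeq2. Its summed level, however, was lower, at 3357 ± 111 CPM in Ctrl and 3056 ± 78 CPM in DACTPL. Members of the integrated stress response also fell. DDIT3, a transcription factor of that response, went from 37.6 ± 4.17 to 23.3 ± 2.04 CPM (adjusted p = 0.00825). PPP1R15A, its phosphatase subunit, went from 80.3 ± 7 to 50.1 ± 3.35 CPM (adjusted p = 1.93e-04), although 2 of the 26 genes of their list rose while 3 fell (2 and 3 adjusted over the list alone). IL1RL1, the interleukin-33 receptor, fell by 1.38 on the log2 scale (SE 0.25, adjusted p = 0.00413) and CSF2RA, a receptor chain for a myeloid growth factor, by 1.07 (SE 0.11, adjusted p = 5.49e-05).

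DNA repair genes fell in 5 of 34 cases and 1 rose (7 and 2 adjusted over the list alone; median -0.11, camera adjusted p = 4.2e-04, and adjusted p = 0.33 with an estimated correlation), among them BRCA1, which went from 96.6 ± 11.3 to 74.3 ± 3.00 CPM. Histone genes rose in 19 of 52 cases (24 adjusted over the list alone; median 0.27, camera adjusted p = 4.3e-12, and adjusted p = 0.33 with an estimated correlation), and with the length trend taken off 19 were called with a median of 0.17. Heat shock genes rose in 4 of 23 cases (10 and 1 lower adjusted over the list alone; median 0.14, turning to -0.02 on the TPM scale; camera adjusted p = 0.047, and adjusted p = 0.13 with an estimated correlation). This call was lost in 11 of 19 other alternatives, with RLE size factors, with the length trend taken off and with any single library left out other than Ctrl replicate 3, DACTPL replicate 2 or DACTPL replicate 3. Hypoxia and glycolysis genes rose in 8 of 30 and 1 fell (8 and 2 adjusted over the list alone; median 0.07, turning to -0.08 on the TPM scale; camera adjusted p = 0.022, and adjusted p = 0.59 with an estimated correlation), a list call lost without Ctrl replicate 1, Ctrl replicate 2 or DACTPL replicate 3 (adjusted p up to 0.079). Stromal markers rose in 4 of 6 (5 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.24 with an estimated correlation), at a summed 31.6 CPM against 21.7 CPM in Ctrl. Of 3 intestinal markers tested 2 rose, and 3 adjusted over the list alone, at a summed 26.9 ± 3.14 CPM against 17.0 ± 0.318 CPM in Ctrl. Of 6 blood markers 2 rose and 1 fell and of 8 luminal prostate markers 2 rose (the same numbers adjusted over the list alone). The summed blood level was 37.8 ± 0.531 CPM against 47.2 ± 2.37 CPM in Ctrl. DNMT3B rose by 0.44 (SE 0.08, edgeR adjusted p = 0.00237), while DCTPP1 stood at 33.1 ± 1.86 CPM and did not pass (0.14, SE 0.14, adjusted p = 0.57).

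In all, 2141 genes differed between DACTPL and Ctrl, 1373 higher and 768 lower, and 465 by 2-fold or more. With limma on log2(TPM + 1), which moved the median of all genes tested to -0.11, the split of 4413 genes was 991 higher and 3422 lower. The count was 1148 without Ctrl replicate 1, 1146 without Ctrl replicate 2 and 1382 without DACTPL replicate 3.

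**Figure D4:**
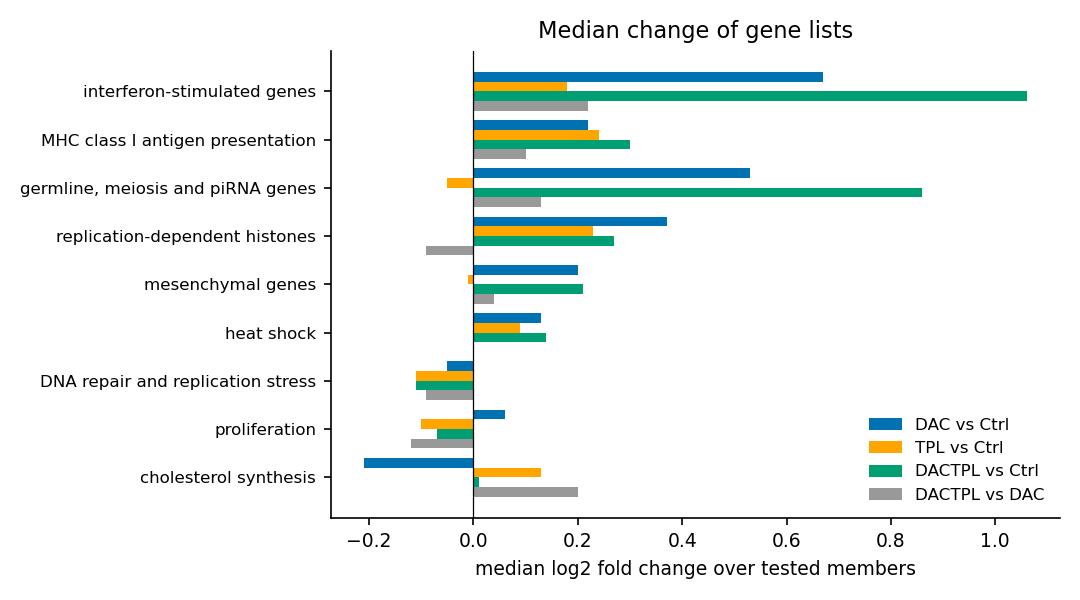
Median log2 fold change of 9 gene lists in DAC vs Ctrl, TPL vs Ctrl, DACTPL vs Ctrl and DACTPL vs DAC, as bars from 0. Interferon-stimulated genes had medians of 0.67, 0.18, 1.06 and 0.22 and cholesterol synthesis genes -0.21, 0.13, 0.01 and 0.20, of which the TPL vs Ctrl medians turned to -0.10 and -0.23, and the cholesterol median of DACTPL vs Ctrl to -0.15, on the TPM scale.

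Whether triptolide added to decitabine was asked by comparing DACTPL with DAC. IFI27 was higher with both drugs, at 16.9 ± 2.72 against 9.88 ± 0.575 CPM (1.72-fold, edgeR adjusted p = 0.0279). MAPK4, an atypical MAP kinase, went from 2.55 ± 0.312 to 5.10 ± 0.192 CPM (1.99-fold), and CPS1, the first enzyme of the urea cycle, from 3.97 ± 0.622 to 7.91 ± 0.648 CPM (1.99-fold). TAGLN, an actin-binding protein of smooth muscle, fell from 9.89 ± 0.608 to 6.30 ± 0.388 CPM, and DUSP5, a phosphatase of ERK kinases, from 82.4 ± 1.74 to 60.6 ± 1.56 CPM. For MAPK4, CPS1, TAGLN and DUSP5 the edgeR adjusted p was also 0.0279, and in each of the 5 genes all 3 libraries of one group lay above all 3 of the other.

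For cancer-testis antigens, edgeR called 0 of 30 over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. As a list they had a median of 0.09 (camera adjusted p = 0.17), which was 0.14 (camera adjusted p = 0.032 at the preset correlation) with each library's length trend taken off. No estimated correlation was used with that correction. Their mean log2 CPM per library was 0.313 ± 0.0959 in DACTPL and 0.0956 ± 0.267 in DAC (SD, n = 3 each), a difference of 0.217 (two-sided exact permutation p = 0.3, where 0.1 is the smallest that 3 against 3 libraries allow). Their summed level was 140.0 ± 2.71 CPM with both drugs and 135 ± 9.67 CPM with decitabine alone (exact permutation p = 0.5). MAGEB2 stood at 6 and 5.94 CPM and H19 at 26.8 and 19.7 CPM. DCTPP1 stood at 33.1 ± 1.86 and 37.6 ± 5.09 CPM (-0.18, SE 0.14, adjusted p = 0.507), DNMT1 at 237 ± 10.8 and 235 ± 9.68 CPM. DNMT3A, DNMT3B, DCK and ERCC3 differed by 0.13 (SE 0.10), 0.00 (SE 0.08), -0.01 (SE 0.13) and -0.10 (SE 0.05) without passing.

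Some lists shifted as groups while 1 member or none was called. Interferon-stimulated genes had a median of 0.22 and 45 of 52 above 0, with IFI27 called over all genes and 2 adjusted over the list alone (camera adjusted p = 3e-08, and adjusted p = 0.54 with an estimated correlation). All 26 cholesterol synthesis genes lay above 0 with a median of 0.20 (camera adjusted p = 1.6e-07, and adjusted p = 0.54 with an estimated correlation), 3 higher when adjusted over the list alone, 9 at an unadjusted p under 0.05 and 0 by edgeR over all genes or by DESeq2. Their summed level was 6502, 7001 and 7479 CPM in DACTPL and 5315, 5339 and 6790 CPM in DAC, so DAC replicate 3 lay above DACTPL replicate 1. Of 40 proliferation genes 5 lay above 0 (median -0.12, camera adjusted p = 1.2e-06, and adjusted p = 0.54 with an estimated correlation), with 0 by edgeR over all genes, over the list alone or by DESeq2 and 11 at an unadjusted p under 0.05. Luminal prostate markers had a median of 0.28 with 8 of 8 above 0 (camera adjusted p = 0.0010, and adjusted p = 0.20 with an estimated correlation), 3 higher adjusted over the list alone and at an unadjusted p under 0.05, and 0 by edgeR over all genes or by DESeq2. Of 3 intestinal markers edgeR called 0 over all genes, with 2 higher adjusted over the list alone, 2 at an unadjusted p under 0.05 and 0 by DESeq2. Their summed level was 23.8 to 30.1 CPM in the DACTPL libraries and 16.9 to 20.1 CPM in the DAC libraries.

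A further 7 lists had a camera adjusted p below 0.05 without an edgeR call over all genes. Their medians were -0.06 for p53 targets, -0.09 for DNA repair, -0.10 for ATF4 and unfolded protein response, 0.10 for class I antigen presentation, 0.11 for hypoxia and glycolysis, -0.06 for TFIIH and RNA polymerase II and -0.09 for histones. With an estimated correlation their adjusted p values were 0.20 for p53 targets, 0.68 for histones and adjusted p = 0.54 for the other 5. DESeq2 called 2 p53 targets and 2 ATF4 genes and 0 in the other 5 lists. At an unadjusted p under 0.05 the higher and lower genes were 1 and 6, 1 and 6, 1 and 5, 6 and 1, 9 and 2, 0 and 2, and 0 and 2 in the order of the medians. Adjusted over the list alone, 3 p53 targets and 2 ATF4 genes were lower and none in the other 5. The class I call was lost without DAC replicate 1, DAC replicate 2 or DACTPL replicate 1 (adjusted p up to 0.37) and the hypoxia call without these or DACTPL replicate 3 (up to 0.18). The histone and TFIIH calls were lost without DAC replicate 2, DACTPL replicate 2 or DACTPL replicate 3 and with the length trend taken off, which turned the histone median to 0.01 (adjusted p = 0.70) and left the TFIIH median at -0.03 (adjusted p = 0.25).

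In all, edgeR called 5 genes between DACTPL and DAC, 3 higher and 2 lower, with 0 of 2-fold or more, against 2419 at an unadjusted p under 0.05, 84 by DESeq2 and 1 (lower) by limma on log2(TPM + 1). Leaving out single libraries gave between 0 and 11 genes. It gave 0 without Ctrl replicate 1, Ctrl replicate 2, TPL replicate 1, DAC replicate 1, DACTPL replicate 1 or DACTPL replicate 2, 1 without DAC replicate 2 or DACTPL replicate 3, 8 without TPL replicate 3 and 11 without DAC replicate 3. Without the replicates numbered 3 of all groups, an alternative chosen after the data were seen, 2134 genes were called, 901 higher and 1233 lower. With the replicate number as a block, an alternative set beforehand, 580 genes were called. The replicate numbers did not pair the samples throughout. In simulated data with known changes, 62% of 1.5-fold and 78% of 2-fold changes were recovered for this comparison, 50 genes for each size. Of 130 calls there, 6 were of unchanged genes, and with DESeq2 19 of 156 were.

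The response to decitabine in the presence of triptolide was given by DACTPL against TPL, which shares no library with DAC against Ctrl. IFI27 rose from 0.527 ± 0.0902 to 16.9 ± 2.72 CPM (log2 fold change 4.99, SE 0.16, edgeR adjusted p = 1.01e-09) and H19 from 0.650 ± 0.231 to 26.8 ± 0.355 CPM (5.36, SE 0.14, adjusted p = 2.05e-10). MAGEB2 was at least 57.3-fold higher and GTSF1 at least 69.7-fold higher than in TPL, where both had 0 counts, and KRT17, with 1 count over the TPL libraries, had a ratio of 159 (95% counting interval 28.3 to 6330). HP, which encodes haptoglobin, fell from 4.81 ± 1.86 to 0.817 ± 0.146 CPM (adjusted p = 0.0101), and SYT8, a synaptotagmin, fell by 1.31 (SE 0.28, adjusted p = 0.0101).

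Of 30 cancer-testis antigens 19 rose and 11 did not pass (22 rose adjusted over the list alone; camera adjusted p = 2.3e-20, and adjusted p = 0.042 with an estimated correlation). Germline genes rose in 16 of 28 cases (17 and 2 lower adjusted over the list alone; camera adjusted p = 6.3e-08, and adjusted p = 0.07 with an estimated correlation). Interferon-stimulated genes rose in 39 of 52 and 1 fell (45 and 2 adjusted over the list alone; median 0.87, camera adjusted p = 3e-30, and adjusted p = 0.07 with an estimated correlation). Cholesterol synthesis fell in 7 of 26 genes and 1 rose (9 and 1 adjusted over the list alone; median -0.16, turning to 0.05 on the TPM scale, where all genes tested had a median of 0.16; camera adjusted p = 1.5e-04, and adjusted p = 0.46 with an estimated correlation). FDPS, the farnesyl pyrophosphate synthase, went from 411 ± 35.8 to 316 ± 23.8 CPM. In the DNA methylation machinery DNMT3B (0.54, SE 0.08, edgeR adjusted p = 9.56e-04), UHRF1 and TDG rose (3 of 17, also adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.15 with an estimated correlation). Camera also called mesenchymal genes (6 of 25 higher, 7 and 2 lower adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.13 with an estimated correlation) and NF-kB and cytokine genes (6 of 27 higher, 9 and 1 lower adjusted over the list alone; adjusted p = 0.030, and adjusted p = 0.46 with an estimated correlation). It called stromal markers (3 of 6 higher, 4 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.15 with an estimated correlation), and TFIIH and RNA polymerase II genes (1 of 24 lower, 0 adjusted over the list alone; median -0.06, turning to 0.14 on the TPM scale; adjusted p = 0.046, and adjusted p = 0.46 with an estimated correlation). The TFIIH call was lost in 6 of 19 other alternatives, without TPL replicate 1, TPL replicate 2, DACTPL replicate 2 or DACTPL replicate 3, with the stricter filter and with the length trend taken off. The NF-kB call was lost without TPL replicate 3 (median 0.02, adjusted p = 0.34), DACTPL replicate 1 or the replicates numbered 3 and with the stricter filter. That of the DNA methylation machinery was lost without TPL replicate 2 and with the length trend taken off, and that of mesenchymal genes without TPL replicate 3 (adjusted p = 0.058). Of 3 intestinal markers 2 rose, and 3 adjusted over the list alone. Histone genes rose in 9 of 52 cases (10 and 1 lower adjusted over the list alone; median 0.03, camera adjusted p = 0.079), and with the length trend taken off 18 of 52 were called with a median of 0.15 (camera adjusted p = 6.7e-09 at the preset correlation). An estimated correlation was not used with that correction.

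In all, 1671 genes differed between DACTPL and TPL, 1101 higher and 570 lower, 430 of them by 2-fold or more, and fold changes were related to gene length (Spearman 0.26). With limma on log2(TPM + 1) the split of 4894 genes was 4772 higher and 122 lower. The count was 955 without TPL replicate 2, 1040 without TPL replicate 1, 981 without DACTPL replicate 2 and 3285 without TPL replicate 3.

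Set side by side, the responses to decitabine without and with triptolide had 627 genes higher in both, against 69 for independent lists (Fisher's exact test across genes, odds ratio 51.6, 95% interval 44.0 to 60.7), and 162 lower in both against 20.4 (odds ratio 14.5, interval 11.7 to 17.9). Another 7 genes were called in opposite directions. Across 1566 genes called in DAC vs Ctrl, the log2 fold changes of DACTPL vs TPL followed those of DAC vs Ctrl with a slope of 1.019 (jackknife SE 0.094 over libraries), and 1332 had the same sign. Genes that rose in DAC vs Ctrl had a median of 0.59 there and 0.58 in DACTPL vs TPL, while genes that fell had -0.39 and -0.16. The first value of each pair comes from the comparison in which the genes were chosen. With the genes chosen in DACTPL vs TPL the medians there were 0.74 and -0.34 against 0.51 and -0.17 in DAC vs Ctrl.

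**Figure D5:**
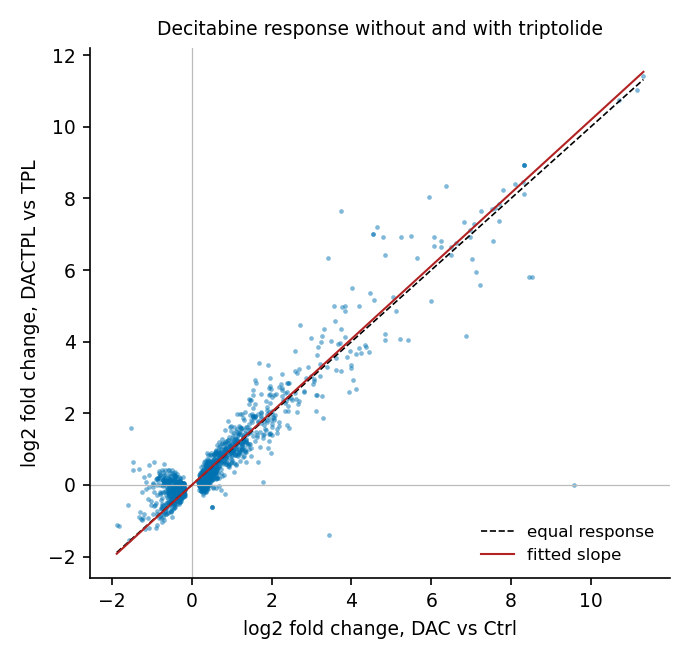
Log2 fold change of DACTPL vs TPL (vertical) against that of DAC vs Ctrl (horizontal) for the 1566 genes called in DAC vs Ctrl, with a dashed line of equal response and the fitted line. The fitted slope was 1.019 and 1332 of the genes had the same sign in both.

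Comparisons that share the Ctrl libraries overlapped as well. DAC and DACTPL had 789 genes higher and 310 lower than Ctrl in common, against 86.1 and 27.5 for independent lists. Their fold changes had a correlation of 0.90 across genes and the same sign in 71.7%. In groups simulated without change, with simulated Ctrl libraries in common, these were 0.47 and 66.6% (covariance 0.3285 against 0.0197). Genes were drawn independently there, so deviations common to many genes of a library were not in the simulation. DAC and TPL shared 60 higher and 54 lower genes (16.7 and 4.5 for independent lists), and TPL and DACTPL shared 115 and 61 (23.1 and 6.0). For these pairs the correlation, 0.19 and 0.24, and the share of the same sign, 65.1% and 65.6%, lay below the simulated 0.47 and 0.50 and 66.2% and 66.2%. Their covariances of 0.0354 and 0.0456 lay above the simulated 0.0205 and 0.0220. A change in 1 group alone lowers a correlation, and the simulated groups held none. The lower correlations therefore do not show that the responses were less alike than without a drug effect. Part of each overlap may come from the shared Ctrl libraries.

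The interaction asked whether the response to decitabine differed with triptolide. EYA4-AS1, an antisense RNA singled out after its values were seen, stood at 25.6 ± 2.28 CPM in Ctrl, 16.7 ± 1 in TPL, 15.5 ± 0.0864 in DAC and 18.2 ± 0.754 in DACTPL, an interaction of 0.85 on the log2 scale (SE 0.11, edgeR adjusted p = 0.0391). The use of strand in counting was not given in the sources used here, so its counts are uncertain against those of its sense partner. DCTPP1 had an interaction of -0.45 (SE 0.20, adjusted p = 0.299), DNMT1 of 0.14 (SE 0.08), DNMT3A of 0.06 (SE 0.14), DNMT3B of 0.09 (SE 0.11), DCK of -0.01 (SE 0.18) and ERCC3 of -0.14 (SE 0.08), and none passed.

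Histone genes lay lower in the interaction, with a median of -0.35 and 4 of 52 above 0 (camera adjusted p = 2.8e-11, and adjusted p = 0.58 with an estimated correlation). Of them 8 were lower adjusted over the list alone, 23 at an unadjusted p under 0.05 and 1 by DESeq2, against 0 by edgeR over all genes. TFIIH and RNA polymerase II genes had a median of -0.16, which turned to 0.15 on the TPM scale where all genes tested had a median of 0.24 (camera adjusted p = 4.9e-04, and adjusted p = 0.53 with an estimated correlation), with 1 gene lower adjusted over the list alone, 9 at an unadjusted p under 0.05 and 0 by edgeR over all genes or by DESeq2. Interaction values were related to gene length with a Spearman correlation of 0.51 across coding genes. With the length trend taken off, the histone median went to 0.00 (camera adjusted p = 0.91) and the TFIIH median to -0.08 (adjusted p = 0.15), so that neither list was called. Interferon-stimulated genes had a median interaction of 0.00 (camera adjusted p = 0.76).

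EdgeR called 1 gene in the interaction, against 2545 at an unadjusted p under 0.05, 119 by DESeq2 and 3670 by limma on log2(TPM + 1), of which 3645 were higher and 25 lower. The count was 950 without TPL replicate 3, 14 without Ctrl replicate 3, 9 without DACTPL replicate 2 and 0 without any other single library.

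All treated libraries together were compared with Ctrl. Interferon-stimulated genes rose in 37 of 52 cases (45 and 1 lower adjusted over the list alone; median 0.68, camera adjusted p = 2.1e-29, and adjusted p = 0.057 with an estimated correlation). Class I genes rose in 10 of 20 (13 adjusted over the list alone; median 0.27, camera adjusted p = 8.5e-08, and adjusted p = 0.057 with an estimated correlation), and histone genes in 24 of 52 (43 adjusted over the list alone; median 0.32, camera adjusted p = 1.6e-18, and adjusted p = 0.22 with an estimated correlation). With each library's length trend taken off, 10 histone genes were called with a median of 0.12. Cancer-testis antigens rose in 3 of 30 by edgeR and 16 by DESeq2 (3 adjusted over the list alone, and 5 higher and 2 lower at an unadjusted p under 0.05; camera adjusted p = 3.8e-15, and adjusted p = 0.057 with an estimated correlation). Germline genes rose in 5 of 28 with 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0074, and adjusted p = 0.28 with an estimated correlation), a list call lost with the stricter filter (adjusted p = 0.58). Heat shock genes rose in 4 of 23 (8 adjusted over the list alone; median 0.08, turning to -0.12 on the TPM scale; camera adjusted p = 0.0074, and adjusted p = 0.057 with an estimated correlation). Hypoxia and glycolysis genes rose in 6 of 30 (7 and 1 lower adjusted over the list alone; median 0.07, turning to -0.14 on the TPM scale; camera adjusted p = 0.014, and adjusted p = 0.57 with an estimated correlation), a list call lost without Ctrl replicate 1 or Ctrl replicate 2 (adjusted p up to 0.091). DNA repair genes fell in 6 of 34 and 1 rose (also adjusted over the list alone; median -0.09, camera adjusted p = 5.1e-04, and adjusted p = 0.39 with an estimated correlation).

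In all, 1637 genes differed between treated and Ctrl libraries, 1008 higher and 629 lower. With limma on log2(TPM + 1), which moved the median of all genes tested to -0.16, the split of 7287 genes was 640 higher and 6647 lower. The count was 392 without Ctrl replicate 1 and 428 without Ctrl replicate 2. Of the 58 list tests called by camera over the 7 comparisons, 2 held with an estimated correlation, those of cancer-testis antigens in DAC vs Ctrl and in DACTPL vs TPL. Members of this list that were silent without decitabine were tested only where a decitabine group expressed them.

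The authors' deposited table for DAC vs Ctrl, made with DESeq2, listed 1740 genes at an adjusted p below 0.05, of which 1454 were also called here. The authors' deposited table for TPL vs Ctrl listed 860 (383 also called here), that for DACTPL vs Ctrl 2370 (2008), that for DACTPL vs TPL 1903 (1556) and that for DACTPL vs DAC 87 (5). No gene called in both had opposite directions in these 5 tables. The authors' deposited table for treatment listed 3633 genes, of which 1506 were also called here and 169 in the opposite direction. In that deposited table the p-value equalled a chi-square test with 3 degrees of freedom in 100% of genes, and the log2 fold change correlated at 0.94 with that of TPL vs Ctrl and at 0.44 with that of all treated libraries against Ctrl (across genes).

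A deposited list of genes with z-scores was chosen by the study on these samples, so its direction is not independent evidence. Of its 697 genes tested here, 576 were higher in DAC than in Ctrl, 681 in DACTPL than in Ctrl, 59 in TPL than in Ctrl and 541 in DACTPL than in TPL. Between DACTPL and DAC, 3 were higher and 1 lower. Over the whole list, genes not tested here included, 503 had their highest group mean score in DACTPL, 174 in DAC and 27 in TPL.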

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

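Of the tests in this part, those of a low level in the Ctrl libraries alone and of fewer cycling cells were chosen only after the result was seen, and the length correction per library was added after the data were seen. A total of 3 results passed a test of the interaction of triptolide and decitabine. EYA4-AS1 had an interaction of 0.85 on the log2 scale, the median of the TFIIH and RNA polymerase II list was -0.16, and that of the replication-dependent histone list was -0.35. Both list results were lost with an estimated correlation between genes (adjusted p = 0.53 and 0.58). EdgeR called 0 of their members over all genes, with 9 and 23 lower at an unadjusted p under 0.05, and DESeq2 called 0 and 1.

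The histone list lay lower in the interaction, with a median of -0.35 and 4 of 52 genes above 0. Fewer cycling cells would lower the proliferation list as well. Its median interaction was -0.02, with 3 of 40 genes higher and 1 lower at an unadjusted p under 0.05. That argues against this explanation, although the spread of the members was not tested. Length bias is a candidate explanation, since the median went to 0.00 once the trend of the interaction on gene length over coding genes was taken off. A low level in the Ctrl libraries alone may account for the same values, because DACTPL differed from DAC by -0.09 and from TPL by 0.03, although TPL replicate 3, at a summed 3886 CPM, lay near Ctrl (3719 to 3830 CPM) and not near the other TPL libraries (4768 and 4882 CPM). Ctrl did not stand apart once each library's length trend was taken off, where TPL vs Ctrl had a median of 0.00 and DACTPL vs TPL 0.15 (18 of 52 called, camera adjusted p = 6.7e-09 at the preset correlation), but on that scale the interaction median was 0.00 too, so this explanation was left open. A lasting effect of the drugs on histone transcripts stays open and was not tested apart from these.

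EYA4-AS1 was lower than Ctrl in each treated group, with log2 fold changes of -0.72 in DAC, -0.62 in TPL and -0.49 in DACTPL. For the interaction, 2 of 25 splits of the 12 libraries, the real one among them, called 1 gene or more. The real one called 1 and the highest other called 7, so chance is not excluded. For TFIIH and RNA polymerase II genes the median went from -0.16 to -0.08 with each library's length trend taken off.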

How the results depend on the processing

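The length correction, the rescaled TPM values, the omission of the replicates numbered 3, the omission of small structural RNAs and the single count of repeated entries were chosen after the data were seen, and the other alternatives before. The cause of a moved value was not tested unless stated. Depth, in M expected counts, was 26.4 to 47 per library. Changes of 1.25-fold were recovered for 14% of simulated genes between DACTPL and DAC and for 16% between DAC and Ctrl, so smaller changes were mostly out of reach. Of 272 calls of named genes over the comparisons, 128 held under every alternative run, 144 were lost under 1 or more and 5 changed sign. The sign changes came with limma on TPM as deposited, a scaling that moved the median of all genes tested in TPL vs Ctrl to -0.29, and there were 0 on rescaled TPM. Of the 5 genes called between DACTPL and DAC none held throughout, each being lost in 9 to 11 of 25 alternatives. Of 58 gene list tests, 34 held under every alternative apart from the estimated correlation and fry. With fry 31 held, and 2 were left with an estimated correlation. In DAC vs Ctrl the estimate was 0.16 for cancer-testis antigens and 0.57 for histones, above the preset 0.01. Calls were also lost where the estimate lay below 0.01. Examples were heat shock genes in DAC vs Ctrl (-0.016, camera adjusted p from 0.0023 to 0.065) and epithelial genes in TPL vs Ctrl (-0.007, from 0.029 to 0.28). A higher correlation between genes therefore does not account for every loss. Over single libraries left out and the other settings, the list tests called ranged from 52 to 70.

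Single libraries left out gave 753 to 2345 genes for DAC vs Ctrl, 25 to 930 for TPL vs Ctrl, 1146 to 3065 for DACTPL vs Ctrl, 0 to 11 for DACTPL vs DAC, 955 to 3285 for DACTPL vs TPL, 0 to 950 for the interaction and 392 to 2275 for all treated libraries vs Ctrl. The genes called in both DAC vs Ctrl and DACTPL vs TPL ranged from 540 to 996, and the slope of the responses from 0.957 to 1.077. Fewer samples lower such counts by construction. Leaving out a library that deviates from its group can raise them, since it lowers the estimated spread.

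Without the replicates numbered 3, the 7 counts were 2806 for DAC vs Ctrl, 1865 for TPL vs Ctrl, 3815 for DACTPL vs Ctrl, 2134 for DACTPL vs DAC, 3709 for DACTPL vs TPL, 2049 for the interaction and 3038 for all treated libraries. An adjusted p below 0.01, stricter by construction, left 656, 44, 992, 0, 746, 0 and 523 in that order, and 411 genes called in both decitabine responses. A fold of 2 or more left 370, 30, 465, 0, 430, 0 and 194.

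DESeq2 moved TPL vs Ctrl to 848, DACTPL vs DAC to 84 and the interaction to 119. Limma on log2(TPM + 1) gave 10270 genes for TPL vs Ctrl, 4413 for DACTPL vs Ctrl, 1 for DACTPL vs DAC, 4894 for DACTPL vs TPL, 3670 for the interaction and 7287 for all treated libraries. With a pseudocount of 0.1 these were 10350, 4314, 1, 5084, 3693 and 7244. RPPH1 alone took 7.51% to 16.6% of TPM per library, and once TPM were rescaled TPL vs Ctrl had 104 genes and the interaction 0 (limma, 2809 at an unadjusted p under 0.05). Fits of the compared groups alone gave 23 genes for TPL vs Ctrl and 784 for DACTPL vs TPL, no expression filter gave 8 for the interaction, and the length correction gave 146 for TPL vs Ctrl and 3 for the interaction.

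Signs turned on the unscaled TPM values in TPL vs Ctrl, where with pseudocounts of 1 and 0.1 PSMB8 was at 0.00 and 0.00, POLR2L at -0.02 and -0.02, MAL2 at -0.03 and -0.03 and HIST2H2AC at -0.04 and -0.04. DNAJB1 in DACTPL vs TPL was at 0.01 with both. With the length trend taken off, the histone median was 0.01 in DACTPL vs DAC and 0.00 in the interaction.

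The replicate numbers were taken from the labels, and the data were checked for a pairing of the samples by them. Deviations of same-numbered libraries correlated between -0.19 and 0.52, with 12 of 18 pairs over 0.1 (4 of 6 for number 1, 2 of 6 for number 2 and 6 of 6 for number 3), and 6 of 12 libraries correlated best with their own number. These values did not show a pairing over all 3 numbers. The libraries numbered 3 of Ctrl, TPL and DAC deviated together, with correlations of 0.34, 0.31 and 0.52. DACTPL replicate 3 correlated with them at 0.14, 0.19 and 0.14, in the order Ctrl, TPL and DAC. DACTPL replicate 2 did so at -0.03, 0.15 and 0.20, so number 3 did not stand apart within DACTPL. As a hint from the data and not from the design, the replicate block raised the counts to 2574 for DAC vs Ctrl, 1288 for TPL vs Ctrl, 3396 for DACTPL vs Ctrl, 580 for DACTPL vs DAC, 2579 for DACTPL vs TPL and 2717 for all treated libraries, and left 1 in the interaction.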

Other observations

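The test of added activation of silent genes was chosen only after the result was seen, as were the length correction per library and the omission of the replicates numbered 3. A set of genes silent without decitabine gained counts with it. Without a count in Ctrl and with at least 10 counts in every library of the other group were 29 genes in DAC, 27 in DACTPL and 0 in TPL, and the reverse held for 0 genes in each pair. TPL and DACTPL differed in the same way for 34 genes, again with 0 in reverse. For comparison, edgeR called 3001 genes between TPL and Ctrl at an unadjusted p under 0.05, 392 after adjustment, and DESeq2 848.

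Small structural RNAs of several classes lay higher in TPL than in Ctrl. Box H/ACA small nucleolar RNAs, which guide pseudouridylation, had a median log2 fold change of 0.65 with 18 of 57 called, box C/D RNAs, which guide methylation of ribose, 0.72 with 3 of 10 called, and small Cajal body RNAs 0.27 with 5 of 13 called. MicroRNA precursors went the other way, with a median of -0.22, 3 of 11 above 0 and 1 called lower. In DACTPL the median of all 96 was 0.21 over Ctrl, and in DAC it was 0.12.

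Among 131 genes without a count in Ctrl and TPL, 67.2% were higher in DACTPL than in DAC. The hypothesis that triptolide adds to the activation of silent genes needed their summed level to be higher in all 3 DACTPL libraries than in all 3 DAC libraries. That level was 56.5 ± 5.41 CPM in DACTPL and 57.3 ± 7.58 CPM in DAC (SD, n = 3 each, exact permutation p = 0.8, where 0.1 is the smallest possible). The libraries overlapped, with the lowest DACTPL library at 50.5 CPM and the highest DAC library at 63.4 CPM, so this condition was not met. By the rule written for the test, such an overlap counts against the hypothesis, although the share of genes leans the other way. The difference lies inside the SD, so a small addition is not excluded.

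Small structural RNAs and histone transcripts were both higher in TPL than in Ctrl. Fewer counts left for other genes cannot be told apart from the rest by leaving the small RNAs out before normalization, which left the histone median at 0.23 but moved none of 168 list medians by more than 0.02. For histones, length bias is a candidate explanation, since their median went from 0.23 to 0.02 with the trend of these fold changes on length over coding genes taken off. For the small RNAs themselves, 88.5% lay above 0 and 18 of 96 fell inside the length range of coding genes, so a difference in size selection cannot be told apart from a change in their level. An effect of triptolide on these transcripts is named by the design and stays open.

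Between DACTPL and DAC, 5 genes were called. Low power for 2-fold changes was neither shown nor excluded, with 78% recovered in simulated data (82% by DESeq2) against a bound of 80% set beforehand. DESeq2 also called more unchanged genes in these data, 19 against 6 by edgeR. In DAC vs Ctrl, 80% were recovered and 370 genes of that size were called. A lower decitabine dose in the combination stays open, because the dose goes with the group, although the slope of the response to decitabine with triptolide on that without was 1.019. A deviation shared by the replicates numbered 3 is a candidate explanation for the low count, as 580 genes were called with the replicate number as a block. That block was the test set beforehand, although the numbers did not pair the samples throughout. Deviations of DAC replicate 3 correlated at 0.14 with DACTPL replicate 3 and at 0.20 with DACTPL replicate 2. The block also raised the counts between other groups, as from 392 to 1288 in TPL vs Ctrl, so the 580 genes cannot single out this explanation. Without the replicates numbered 3, 2134 genes were called, which cannot decide. Leaving out libraries that deviate from their groups lowers the estimated spread, and counts rose in every comparison, as from 392 to 1865 in TPL vs Ctrl. The biological reading, that triptolide changed little in cells given decitabine, was not tested apart from these.

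For groups of 3 libraries the 10 splits are too few for a share under 0.05. The real split called 1566 genes in DAC vs Ctrl, 392 in TPL vs Ctrl, 2141 in DACTPL vs Ctrl and 5 in DACTPL vs DAC, and the highest other split called 0 in each of them. In DACTPL vs TPL the real split called 1671 and the highest other 1184, for TPL replicates 1 and 2 with DACTPL replicate 1 against the rest. These 3 were the libraries of the pair of groups with negative length correlations (-0.38, -0.37 and -0.20). For all treated libraries against Ctrl, 1 of 25 splits, the real one, called as many as 1637 genes and the highest other called 0. The real split alone makes a share of 0.04, the smallest that 25 splits allow. The other splits moved the labels of all 4 groups, so libraries with and without decitabine could share a group and widen its spread. Counts of 0 there may come from this mixing, so chance was not excluded.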
